A study of Homo sapiens with 3 samples.

How the data were processed

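Single-cell 5' gene expression libraries of peripheral blood mononuclear cells were analysed, 1 library for each of 3 groups: a healthy control, a kidney transplant recipient under standard of care and an operationally tolerant kidney transplant recipient. Per the file headers, the deposited matrices hold raw counts of unique molecular identifiers per gene and barcode. The submitters' processing notes name Cell Ranger, Seurat and the genome build hg38, and the matrix headers give Cell Ranger version 3.1.0 for the healthy control and tolerant libraries and 6.1.1 for the standard of care library. The number of barcodes in each matrix equals the cell number given in the labels, so the matrices hold called cells, and empty droplets were not used here. The features tables of the 3 libraries hold 36601 genes, of which 34616 (94.6%) have their identifier in annotation release 29, from which coordinates were taken.

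Barcodes with under 200 detected genes or over 15% mitochondrial counts were removed. Doublets were scored with Scrublet through scanpy 1.11.5, and the highest scores were removed at an assumed rate of 0.8% per 1000 barcodes. The automatic threshold, not used here, marked 431, 4 and 779 barcodes in the healthy control, standard of care and tolerant libraries and did not work in the second. This removed 671 doublets from the healthy control, 190 from the standard of care and 737 from the tolerant library, and 117, 60 and 260 barcodes exceeded the mitochondrial limit. The kept cells held 40333437, 16894429 and 46526641 counts, with medians of 4524, 3500 and 4740 per cell. The 21585 kept cells were integrated by reciprocal principal component analysis in Seurat 5.3.0 (R 4.3.3) with 2000 variable genes and 30 components, and grouped by Louvain clustering at resolution 1 into 28 clusters. B-like cells were clustered again at resolution 0.5.

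Clusters were named from fixed marker lists by the mean of the 4 highest log2 folds among markers detected in at least 10% of the cluster's cells. At least 3 such markers were required, with at least 1 own marker and no other class with more among the top 10 genes. This naming score was set after the data were examined, whereas the markers, gene lists, size rule and most alternatives were fixed before the data were examined. CD8A, CD8B and LINC02446 were not used to decide between the CD8 classes. Clusters that failed the rule were left unnamed.

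Counts were summed per library and class and scaled by the library total of the class (CPM), and log2 ratios were computed with a pseudocount of 5. With 1 library per group no test was made. Exact Poisson intervals were given for CPM, exact Clopper-Pearson intervals for shares and conditional binomial intervals for ratios, all at 95%, and a count of 0 was bounded with a floor of 3 counts. The named-genes rule took genes at least 1 log2 unit higher or lower in a library than in both others, with both ratio intervals on that side of 0 and at least 50 CPM in at least 1 library. Against free RNA, a gene also had to reach, in the library where it was highest, 10% of its highest CPM among the classes of that library. Only named classes with enough cells in every library entered this check. The plasma cell, plasmacytoid dendritic cell, progenitor, cycling and erythroid classes did not. The rule was applied in the 5 classes with the most cells in their smallest library, among those with at least 200 cells in every library. Immunoglobulin, T cell receptor, HLA, KIR, ribosomal, mitochondrial, haemoglobin and sex-linked genes, genes with common whole-gene deletions and clone-named loci were not named by it, but members of the fixed lists could serve as examples. Ranked by the smaller of the 2 differences, the rule named the top 3 genes in each direction for the tolerant library and the top 2 for the others, which gave 70 entries of 54 genes.

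The 21 fixed gene lists were read in 8 cell sets as the median log2 ratio of members with at least 10 CPM in at least 1 library, where at least 5 members were measured. Each median was placed among 10000 random lists matched in 20 expression bins, as a description of these libraries. The choice of which shares and lists answer the comparisons, the central range of random lists and the lists drawn were set after the values had been seen. In simulated data, 50 genes per class were altered at each fold. The size rule found 0% of genes altered 1.5-fold, a change below its limit of 1 log2 unit. It found 90 to 96% of those altered 2.5-fold, 100% at 4-fold, 98 to 100% at 8-fold and 0% of unaltered genes. Of 100 unaltered lists per class, 1 to 6 lay outside the central range. All simulated libraries were drawn from the pooled profile of the class, so these values cover counting error only. The free RNA condition and the ranking were not part of the simulation.

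The alternatives were stricter barcode filters, no doublet removal, no integration, other cluster resolutions, thinned counts, median-of-ratios scaling, totals without ribosomal, mitochondrial, immunoglobulin and T cell receptor genes, another pseudocount and other minimum values. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used. Sequence variants were not analysed here.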

Results

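Peripheral blood mononuclear cells, the lymphocytes and monocytes that remain after density separation of blood, were profiled by droplet-based single-cell RNA sequencing in 3 libraries, 1 per group. The groups were a healthy control, a kidney transplant recipient with a stable graft under immunosuppressive drugs (standard of care), and a kidney transplant recipient with operational tolerance, the state in which a graft keeps working without such drugs. The comparisons address which cell classes and which expression differences set the tolerant library apart from the others. The healthy control library held 9242 barcodes and 45529952 unique molecular identifiers (UMIs, each standing for 1 captured RNA molecule), with a median of 4573 UMIs and 1743 genes per barcode. The standard of care library held 5118 barcodes and 18560863 UMIs, with medians of 3376.5 UMIs and 1362 genes. The tolerant library held 9746 barcodes and 53358123 UMIs, with medians of 4773.5 UMIs and 1822 genes. After filtering, 8408, 4462 and 8715 cells were kept in the healthy control, standard of care and tolerant libraries.

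There were no replicates, so no test between groups was run, each difference is one between libraries, and the 95% intervals (exact Clopper-Pearson for shares, exact Poisson for expression) cover counting error only. The standard of care library also stood apart technically. Its matrix was written by Cell Ranger 6.1.1 and the other 2 by version 3.1.0, and the labels give it 212063 reads per cell against 47863 in the healthy control and 49033 in the tolerant library. For this library, group, handling, depth and software version cannot be told apart.

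B-like and plasma cell-like cells took larger shares of the tolerant library than of either other library, and MAIT-like cells (mucosal-associated invariant T cells, innate-like lymphocytes that recognise microbial vitamin metabolites) took a smaller one. B-like cells made up 8.80% of the tolerant library (767 cells, 95% interval 8.21 to 9.42%), against 4.45% of the healthy control (374 cells, 4.02 to 4.91%). They made up 1.99% of the standard of care library (89 cells, 1.60 to 2.45%). Plasma cell-like cells, the antibody-secreting end of the B lineage, numbered 60 in the tolerant library (0.688%, 0.526 to 0.885%) and 2 in the healthy control (0.0238%, 0.00288 to 0.0859%). The share was 28.9-fold higher in the tolerant library, with an interval of 7.67 to 244. In the standard of care library 0 of 4462 cells were plasma cell-like, for which a floor of 3 cells, or 0.0672%, was used. Against that floor the tolerant share was at least 10.2-fold higher, and the 95% counting interval of the ratio began at 8.07. MAIT-like cells made up 0.390% of the tolerant library (34 cells, 0.270 to 0.545%), 4.41% of the healthy control (371 cells, 3.98 to 4.87%) and 3.47% of the standard of care library (155 cells, 2.96 to 4.05%). Without integration of the libraries, 0% of the standard of care cells were named B-like and 0% MAIT-like, so these shares of that library rest on the integration.

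Within the T lineage, naive classes took smaller shares of the tolerant library and effector CD8 T-like cells a larger one, while the order for memory CD4 T-like cells depended on the clustering. Naive CD4 T-like cells made up 11.03% of the tolerant cells (10.4 to 11.7%), against 16.3% (15.5 to 17.1%) in the healthy control and 16.1% (15.05 to 17.2%) in the standard of care library. Naive CD8 T-like cells made up 1.10%, 2.70% and 2.80% of the tolerant, healthy control and standard of care libraries. Memory CD4 T-like cells made up 17.6% of the tolerant (16.8 to 18.4%), 11.8% of the healthy control and 14.6% of the standard of care cells. Effector CD8 T-like cells made up 22.8% of the tolerant, 20.1% of the healthy control and 12.4% of the standard of care cells. Regulatory T-like cells, which restrain other T cells, made up 1.50%, 1.91% and 1.57% in the same order, with a ratio of 0.785 for tolerant over healthy control (0.619 to 0.995). Gamma-delta T-like cells made up 2.60%, 4.22% and 3.79%, and T-like cells as a whole 57.0%, 61.5% and 54.7%. The boundary between naive and memory CD4 T-like cells moved with the clustering. At resolution 2 the memory share was 11.1% in both the tolerant and the healthy control library and 13.2% in the standard of care library, so it was no longer larger in the tolerant library than in either other. At resolution 0.5 the naive shares were 2.25%, 8.87% and 8.67% in the tolerant, healthy control and standard of care libraries.

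Among the other classes, CD14 monocyte-like cells (classical monocytes) took a smaller share of the tolerant library, at 5.79% (5.31 to 6.31%) against 9.91% in the healthy control and 10.7% in the standard of care library. CD16 monocyte-like cells (non-classical monocytes) made up 4.35% of the tolerant, 2.40% of the healthy control and 3.47% of the standard of care cells. NK-like cells made up 14.8%, 13.7% and 18.8% in the same order, of which NK CD56dim-like cells were 13.7%, 13.01% and 18.04% of all kept cells and NK CD56bright-like cells 1.07%, 0.678% and 0.717%. Cycling-like cells made up 0.688% of the tolerant, 0.226% of the healthy control and 0.157% of the standard of care cells. Conventional dendritic cell-like cells made up 0.574%, 0.904% and 0.784%, and plasmacytoid dendritic cell-like cells 0.229%, 0.119% and 0.0672%. Progenitor-like cells numbered 2 in the tolerant, 21 in the healthy control and 9 in the standard of care library. Platelet-like barcodes made up 2.54%, 3.22% and 0.762% of the tolerant, healthy control and standard of care libraries, and erythroid-like cells 0.0918%, 0.131% and 1.73%. Clusters left without a name held 4.41%, 3.20% and 6.68% of the cells. Cluster 14 held 2.66%, 1.77% and 1.90%, cluster 18 1.62%, 1.32% and 0.179%, and cluster 20 0.126%, 0.107% and 4.59%.

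**Figure D1:**
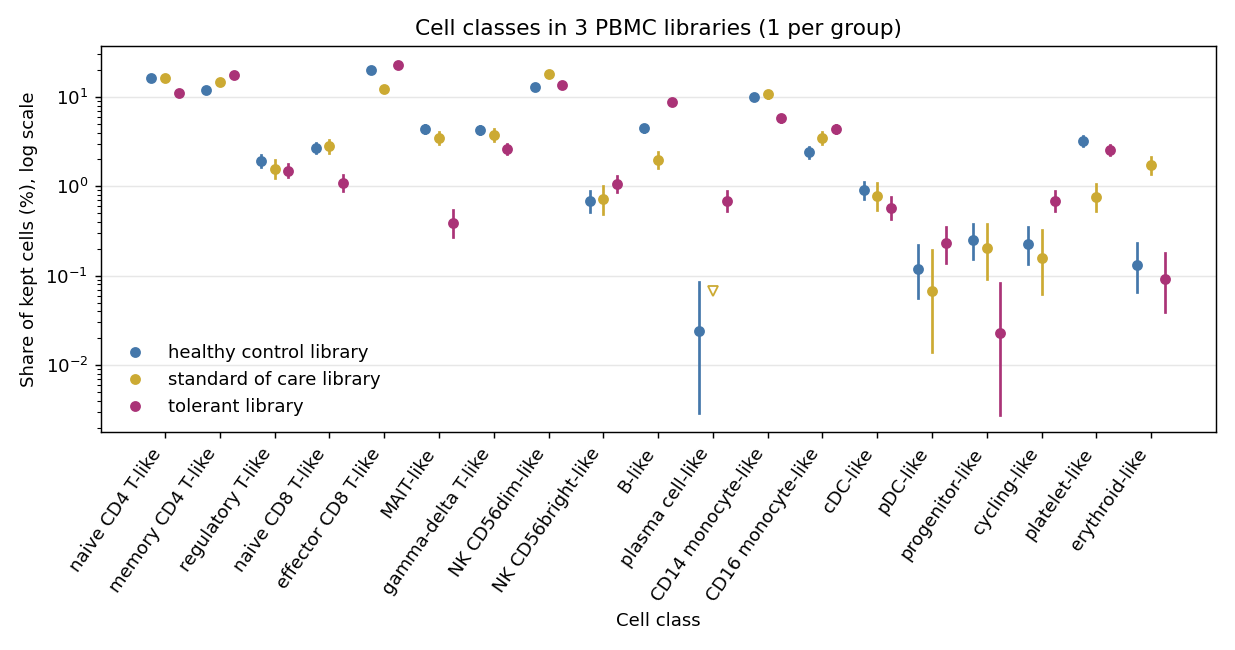
Share of kept cells in each named class (y axis, percent, log scale) for the healthy control, standard of care and tolerant libraries, with exact 95% binomial intervals as bars. The open triangle marks the floor of 3 cells used for 0 plasma cell-like cells in the standard of care library (0.0672%); B-like cells reach 8.80% and MAIT-like cells 0.390% in the tolerant library.

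Within the B-like cells, naive B-like cells (fixed markers such as TCL1A and IGHD) made up 27.8% in the tolerant library (213 of 767 cells, 24.6 to 31.1%), 18.4% in the healthy control (69 of 374, 14.6 to 22.8%) and 38.2% in the standard of care library (34 of 89, 28.1 to 49.1%). Memory B-like cells made up 52.3%, 58.0% and 48.3% in the same order. Atypical B-like cells, with fixed markers such as FCRL5 and SOX5, made up 4.95% of the tolerant (3.53 to 6.74%), 17.6% of the healthy control (13.9 to 21.9%) and 7.87% of the standard of care B-like cells (3.22 to 15.5%). Cells in B clusters without a name made up 14.99%, 5.88% and 5.62%. No B sub-cluster was named transitional B-like by the naming rule, which does not show that such cells were absent.

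Genes reported in earlier work as B cell markers of kidney graft tolerance were fixed as a list of 15 and were higher in the tolerant library over all cells, but not within its B-like cells against the healthy control. Over all kept cells, 13 members were measured and their median log2 ratio was 0.75 for tolerant over healthy control and 1.69 for tolerant over standard of care. Both lay at percentile 100 among 10000 matched random lists. MS4A1, which encodes the B cell surface protein CD20, stood at 199 CPM (counts scaled by the library total) in the tolerant library (195 to 203), 109 in the healthy control (106 to 112) and 23.9 in the standard of care library (21.6 to 26.4). TCL1A, a gene of naive B cells, stood at 35.1, 12.3 and 0.592 CPM in the same order. Within B-like cells, with 12 members measured, the median was -0.07 against the healthy control (percentile 17.8) and 1.06 against the standard of care library (percentile 98.5). Against the healthy control, 1 member was at least 1 log2 unit higher, 1 at least 1 unit lower and 10 lay between. In B-like cells TCL1A stood at 342 CPM in the tolerant (325 to 360), 219 in the healthy control (199 to 240) and 25.3 in the standard of care library (10.9 to 49.9). MS4A1 stood at 1925, 2007 and 1161 CPM. In memory CD4 T-like cells 5 members reached the minimum, with medians of -0.15 against the healthy control and 1.21 against the standard of care library. The standard of care values in B-like cells rest on 89 cells and 315979 UMIs. HBB, a haemoglobin gene of erythrocytes, stood at 6311 CPM in them against 18.8 in the healthy control and 7.13 in the tolerant library.

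MHC class II presentation genes, which display peptides to CD4 T cells, were higher in T and NK cells of the tolerant library than of the healthy control. In NK CD56dim-like cells 6 of 7 measured members were at least 1 log2 unit higher and the list median was 1.85. The medians were 1.31 in naive CD4 (4 of 6 members), 1.44 in memory CD4 (4 of 6) and 1.29 in effector CD8 T-like cells (4 of 7), each at percentile 100. With no minimum CPM the medians were 0.69 in naive CD4 and 0.84 in memory CD4 T-like cells. HLA-DRA stood at 318 CPM in tolerant effector CD8 T-like cells, against 50.9 in the healthy control and 26.1 in the standard of care library, and CD74, the invariant chain that guides MHC class II assembly, at 2131, 821 and 982 CPM. In the professional antigen-presenting classes the medians for tolerant over healthy control were smaller, at 0.29 in B-like, 0.29 in CD14 monocyte-like and -0.07 in CD16 monocyte-like cells. Against the standard of care library the medians were 0.83 in NK CD56dim-like, 1.67 in naive CD4, 2.08 in memory CD4 and 1.67 in effector CD8 T-like cells. S100A8, a monocyte transcript, also moved with this list: it stood at 30.5 CPM in tolerant effector CD8 T-like cells, against 10.4 in the healthy control and 2.56 in the standard of care library.

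In naive CD4 T-like cells the tolerant library stood apart by CAPG, TNFRSF4 and EPSTI1 on the higher side and SMDT1, CHPT1 and FHIT on the lower side. CAPG (ENSG00000042493, chromosome 2, 85394748 to 85418432), an actin-capping protein gene and fixed marker of NK CD56bright cells, stood at 80.4 CPM in the tolerant (73.3 to 88.1), 14.5 in the healthy control (11.9 to 17.6) and 1.41 in the standard of care library (0.385 to 3.62). TNFRSF4, which encodes the costimulatory receptor OX40 and was a fixed marker of memory CD4 T cells, stood at 57.9, 16.6 and 7.42 CPM, and EPSTI1, an interferon-responsive gene, at 71.3, 21.6 and 18.4 CPM. SMDT1 (ENSG00000183172, chromosome 22, 42079691 to 42084284), a subunit gene of the mitochondrial calcium uniporter, stood at 80.8 CPM in the tolerant (73.6 to 88.4), 228 in the healthy control (218 to 240) and 248 in the standard of care library (230 to 267). CHPT1 stood at 2.93, 14.4 and 51.2 CPM and FHIT, a fixed marker of naive CD4 T cells, at 23.8, 59.9 and 67.5 CPM. Naive and central memory T genes had a median of -0.39 for tolerant over healthy control (10 members, percentile 0), with CCR7, the lymph node homing receptor, at 336 CPM in the tolerant and 567 in the healthy control library. T cell inhibitory receptor genes had a median of 0.68 (6 members, percentile 99.98), with TIGIT, also a fixed marker of regulatory T cells, at 65.5 and 26.1 CPM. Most naive CD4 T-like cells came from cluster 7 in the healthy control (742 of 1369) and standard of care libraries (384 of 719) and from cluster 3 in the tolerant library (770 of 961). FHIT was among the top 10 genes of cluster 7. The named genes were not examined within single clusters, so the cluster mix could account for part of these differences.

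Memory CD4 T-like cells of the tolerant library carried more RNA of cytotoxic genes, which arm T and NK cells to kill target cells, and so did classes that are not cytotoxic. The cytotoxic list had medians for tolerant over healthy control of 0.99 in naive CD4 T-like cells (4 of 8 members at least 1 log2 unit higher, percentile 100) and 1.20 in B-like cells (4 of 5, percentile 99.97), where GNLY stood at 77.6 against 20.2 CPM. The B-like class included a sub-cluster led by T cell genes such as IL7R, CD3E and GZMK, with 35 of 767 tolerant and 10 of 374 healthy control cells. In memory CD4 T-like cells, of 15 cytotoxic effector genes, 7 were at least 1 log2 unit higher and 1 at least 1 unit lower than in the healthy control, with a median of 0.99. Against the standard of care library 12 were at least 1 unit higher, with a median of 2.21. Both medians lay at percentile 100. GNLY (ENSG00000115523, chromosome 2, 85685175 to 85698854), which encodes the cytolytic protein granulysin, stood at 2353 CPM in the tolerant (2321 to 2387), 430 in the healthy control (413 to 447) and 334 in the standard of care library (313 to 357). CX3CR1, the fractalkine receptor gene and a fixed marker of NK CD56dim cells, stood at 172 CPM (164 to 182), 33.8 (29.2 to 38.9) and 0.367 (0.00929 to 2.04). ZNF683, a transcription factor gene of tissue-resident and cytotoxic T cells, stood at 100.5, 9.01 and 18.3 CPM. On the lower side were PASK at 11.9, 40.9 and 75.2 CPM, SMDT1 at 78.1, 224 and 198 CPM, and AUTS2 at 9.94, 25.6 and 57.6 CPM. GZMK, a granzyme gene and fixed marker of effector CD8 T cells, went the other way, at 149 CPM in the tolerant and 344 in the healthy control library. Most memory CD4 T-like cells of the tolerant library came from cluster 8 (841 of 1535), against 329 of 996 in the healthy control and 103 of 651 in the standard of care library, where cluster 2 held most. Without integration the median of the cytotoxic list against the healthy control was -0.42, GNLY stood at -0.46 and CX3CR1 at -0.68 on the log2 scale. The direction thus depends on which cells were placed in the class.

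Effector CD8 T-like cells of the tolerant library stood apart by CD160, CAPG and LINC02446 on the higher side and PDE4D, MT2A and FOSL2 on the lower side. CD160 (ENSG00000117281, chromosome 1, 145719471 to 145739288), a receptor gene of cytotoxic lymphocytes, stood at 91.5 CPM in the tolerant (85.5 to 97.8), 9.54 in the healthy control (7.44 to 12.1) and 6.15 in the standard of care library (3.18 to 10.7). CAPG stood at 61.4, 5.45 and 1.02 CPM, and LINC02446, a long non-coding RNA, at 534, 139 and 113 CPM. LINC02446 was on the fixed marker list of naive CD8 T cells but was among the top 10 genes of both clusters of this class. PDE4D, a cyclic AMP phosphodiesterase gene, stood at 9.39 CPM in the tolerant (7.54 to 11.6), 40.6 in the healthy control (36.1 to 45.5) and 163 in the standard of care library (145 to 182). MT2A, a metallothionein gene, stood at 149, 425 and 1258 CPM, and FOSL2, an AP-1 transcription factor gene, at 11.8, 34.9 and 204 CPM. Inhibitory receptor genes went both ways against the healthy control, with a median of -0.02 over 8 members: PDCD1, which encodes PD-1, stood at 9.18 CPM in the tolerant and 38.7 in the healthy control library. The cytotoxic list had a median of -0.12 against the healthy control (percentile 1.13), with PRF1, the perforin gene, at 484 against 893 CPM, but was 0.16 in cluster 0 alone. It was 1.28 against the standard of care library. Regulatory T cell genes had a median of -0.43 (6 members, percentile 0.06), which was 0.032 with no minimum CPM. Cluster 0 held most effector CD8 T-like cells in the tolerant (1147 of 1985) and standard of care libraries (420 of 552) and cluster 1 in the healthy control (1046 of 1690).

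In NK CD56dim-like cells the tolerant library was higher in LINC02446, GATD3A and LGALS3 and lower in CXCR4, MT2A and SLA2. LINC02446 (ENSG00000256039, chromosome 12, 10553363 to 10558049) stood at 198 CPM in the tolerant (186 to 211), 20.03 in the healthy control (15.98 to 24.8) and 18.02 in the standard of care library (12.98 to 24.4). This gene was among the top 10 genes of the effector CD8 T-like clusters 0 and 1. Whether T cells placed in the NK CD56dim-like class contributed to its level was not tested. GATD3A stood at 54.6, 0.477 and 7.29 CPM, but has a near-identical copy on the same chromosome, so its value is uncertain. LGALS3, which encodes the lectin galectin-3, stood at 115, 27.2 and 21.9 CPM. CXCR4 (ENSG00000121966, chromosome 2, 136114349 to 136118165), the chemokine receptor of bone marrow retention, stood at 7.83 CPM in the tolerant (5.57 to 10.7), 93.5 in the healthy control (84.4 to 103) and 286 in the standard of care library (264 to 308). MT2A stood at 125, 391 and 669 CPM and SLA2, a negative regulator of antigen receptor signalling, at 42.4, 138 and 169 CPM. CXCR4 is also a glucocorticoid response gene, and that list had a median of -0.84 for tolerant over healthy control (9 members, percentile 0), with TSC22D3, the glucocorticoid-induced leucine zipper gene, at 124 against 369 CPM. The cytotoxic list had a median of 0.27 against the healthy control, with GNLY at 18449 and 9312 CPM and GZMB at 1626 and 2448 CPM. HBB stood at 402 CPM in these cells of the tolerant, 34.6 of the healthy control and 1455 of the standard of care library. Cluster 4 held most NK CD56dim-like cells in the tolerant (727 of 1197) and standard of care libraries (689 of 805) and cluster 6 in the healthy control (787 of 1094).

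CD14 monocyte-like cells of the tolerant library were higher in LINC02432, CXCL10 and FOLR3 and lower in THBS1, TMEM176A and EREG. FOLR3 (ENSG00000110203, chromosome 11, 72114869 to 72139892), a secreted folate receptor gene, stood at 350 CPM in the tolerant (326 to 375), 25.9 in the healthy control (20.8 to 32.0) and 109 in the standard of care library (94.2 to 125). LINC02432 stood at 96.8, 17.9 and 1.65 CPM. CXCL10, an interferon-induced chemokine gene, stood at 52.3, 4.77 and 10.4 CPM, but without integration its log2 ratios were -0.74 against the healthy control and -1.35 against the standard of care library. THBS1 (ENSG00000137801, chromosome 15, 39581079 to 39599466), which encodes the matrix protein thrombospondin 1, stood at 16.3 CPM in the tolerant (11.5 to 22.3), 115 in the healthy control (104 to 127) and 2332 in the standard of care library (2262 to 2403). TMEM176A stood at 4.71, 52.2 and 40.1 CPM, and EREG, the growth factor gene epiregulin, at 0.428, 8.64 and 95.1 CPM. S100 and calprotectin-family genes had a median of -0.02 against the healthy control and 0.54 against the standard of care library (10 members), with S100A8 at 13123, 8503 and 3653 CPM. Platelet RNA moved with this class: all 8 platelet genes were at least 1 log2 unit higher than in the healthy control, with a median of 1.55, and PPBP stood at 322, 75.1 and 94.0 CPM.

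**Figure D2:**
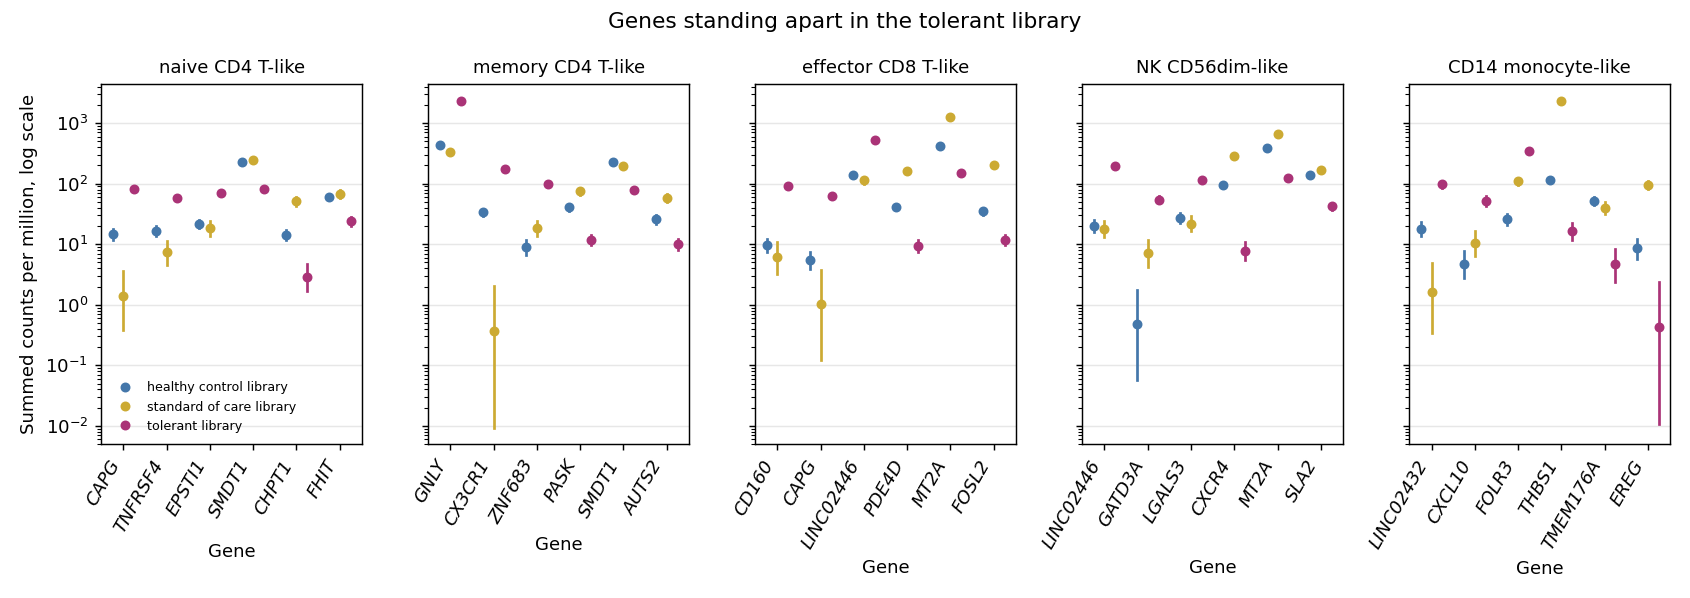
Summed counts as CPM (y axis, log scale) of the genes named by the size rule in the tolerant library, in 5 classes, for the healthy control, standard of care and tolerant libraries, with exact Poisson 95% intervals as bars. In each panel the 3 genes on the left are higher and the 3 on the right lower in the tolerant library than in both others, as for CXCR4 at 7.83 against 93.5 and 286 CPM.

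The standard of care library was set apart by genes that cells switch on within minutes to hours of a stimulus. Immediate early and AP-1 genes had medians, for standard of care over healthy control, of 3.71 in naive CD4 (9 of 10 members at least 1 unit higher), 3.31 in memory CD4 (11 of 12) and 3.19 in effector CD8 T-like cells (11 of 12). They were 2.01 in NK CD56dim-like cells (11 of 12) and 1.83 in CD14 monocyte-like cells (11 of 13), each at percentile 100. JUND (ENSG00000130522, chromosome 19, 18279760 to 18281622) stood at 1909 CPM in standard of care naive CD4 T-like cells (1859 to 1961), 14.1 in the healthy control (11.5 to 17.1) and 16.0 in the tolerant library (12.9 to 19.6). FOS stood at 548, 1.67 and 8.27 CPM there and at 1063, 8.83 and 11.7 CPM in memory CD4 T-like cells. NR4A2, an orphan nuclear receptor gene, stood at 787, 6.68 and 4.22 CPM in effector CD8 T-like cells. Inflammatory cytokine and NF-kB genes had medians of 1.96 in NK CD56dim-like, 2.79 in memory CD4, 2.67 in effector CD8 T-like and 1.86 in CD14 monocyte-like cells, with TNFAIP3, a brake on NF-kB, at 1202 against 71.4 CPM in memory CD4 T-like cells. With no minimum CPM the medians of this list were 0.27 in memory CD4 and 1.04 in effector CD8 T-like cells. Calcineurin-NFAT targets, the genes that drugs such as tacrolimus restrain, had medians of 1.77 in memory CD4 (7 of 14 members measured) and 2.31 in effector CD8 T-like cells (6 of 14). With no minimum CPM both fell to near 0, and the memory CD4 median for tolerant over standard of care turned from -1.66 to 0.030. CD40LG, the activation ligand of helper T cells, went the other way and stood at 59.4 against 160 CPM in memory CD4 T-like cells.

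Glucocorticoid response genes were higher in the same library, with medians over the healthy control of 1.56 in NK CD56dim-like cells, 2.12 in naive CD4, 2.33 in memory CD4 and 2.11 in effector CD8 T-like cells, and 1.39 in CD14 monocyte-like cells. PER1, a clock gene induced by glucocorticoids and by cyclic AMP, stood at 285 CPM in standard of care NK CD56dim-like cells (264 to 308), 7.15 in the healthy control (4.83 to 10.2) and 4.82 in the tolerant library (3.09 to 7.17). FKBP5, also a steroid target, went both ways: it stood at 23.2 against 44.6 CPM in those cells, 59.9 against 60.5 CPM in CD14 monocyte-like cells and 126 against 91.3 CPM in naive CD4 T-like cells. TGF-beta pathway genes had medians of 0.81 in NK CD56dim-like, 1.24 in naive CD4, 1.69 in memory CD4 and 1.19 in effector CD8 T-like cells and 0.42 in CD14 monocyte-like cells, with TGFB1 at 1331 against 131 CPM in memory CD4 T-like cells. Heat shock genes had medians between -0.93 in CD14 monocyte-like and 0.37 in effector CD8 T-like cells. In CD14 monocyte-like cells G0S2, an inhibitor of lipolysis, stood at 2003 CPM (1939 to 2069), 0.894 in the healthy control (0.184 to 2.61) and 4.71 in the tolerant library (2.35 to 8.43). CXCL8, the neutrophil-attracting chemokine gene, stood at 312, 0.894 and 0.428 CPM. HBB was also highest in standard of care CD14 monocyte-like cells, at 2180 CPM against 1106 in the healthy control and 6.43 in the tolerant library. Unlike these lists, it thus set the healthy control far above the tolerant library.

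Cytotoxic genes were lower in T and NK cells of the standard of care library, and interferon response genes in its T cells and CD14 monocyte-like cells. In CD14 monocyte-like cells the cytotoxic list went the other way, with a median over the healthy control of 0.73 (percentile 99.69). Of 15 cytotoxic genes, 9 in NK CD56dim-like and 12 in effector CD8 T-like cells were at least 1 log2 unit lower than in the healthy control, with medians of -1.17 and -1.83. GZMA, the granzyme A gene, stood at 19.4 CPM in standard of care memory CD4 T-like cells (14.6 to 25.4), 321 in the healthy control (307 to 336) and 652 in the tolerant library (635 to 669). CX3CR1, a fixed marker of NK CD56dim-like cells, stood at 20.2 CPM in them, against 721 and 760 CPM, and at 3.59 against 360 and 241 CPM in effector CD8 T-like cells. It had 0 counts in CD14 monocyte-like cells, where the floor of 3 counts is 1.65 CPM. MYOM2, another marker of NK CD56dim-like cells, had 0 counts in NK CD56dim-like cells, where the floor of 3 counts is 1.29 CPM, against 223 CPM in the healthy control (209 to 238) and 75.1 in the tolerant library (67.7 to 83.1). CISH, a feedback inhibitor of cytokine signalling, stood at 0.353 CPM in naive CD4 T-like cells (0.00895 to 1.97), 70.5 in the healthy control and 161 in the tolerant library, and at 1.47, 139 and 196 CPM in memory CD4 T-like cells. LINC00861 in naive CD4 T-like cells (36.4, 512 and 367 CPM), GIMAP4 in effector CD8 T-like cells (26.1, 498 and 439 CPM) and GIMAP8 in CD14 monocyte-like cells (1.10, 128 and 85.7 CPM), the last 2 encoding immune GTPases, were lower in the same direction. Type I interferon response genes had medians over the healthy control of -0.47 in NK CD56dim-like, -0.96 in naive CD4, -0.97 in memory CD4 and -0.84 in effector CD8 T-like cells and -0.71 in CD14 monocyte-like cells. The NK CD56dim-like median (percentile 3.78) and the median over all cells (-0.41, percentile 12.38) lay inside the central 95% of random lists. IFIT2 went the other way in NK CD56dim-like cells, at 277 against 28.6 CPM. These classes leave out cluster 20, led by interferon genes such as IFIT2 and OASL, which held 205 standard of care and 9 healthy control cells. For tolerant over healthy control the same list lay between -0.27 and 0.08 in these classes.

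**Figure D3:**
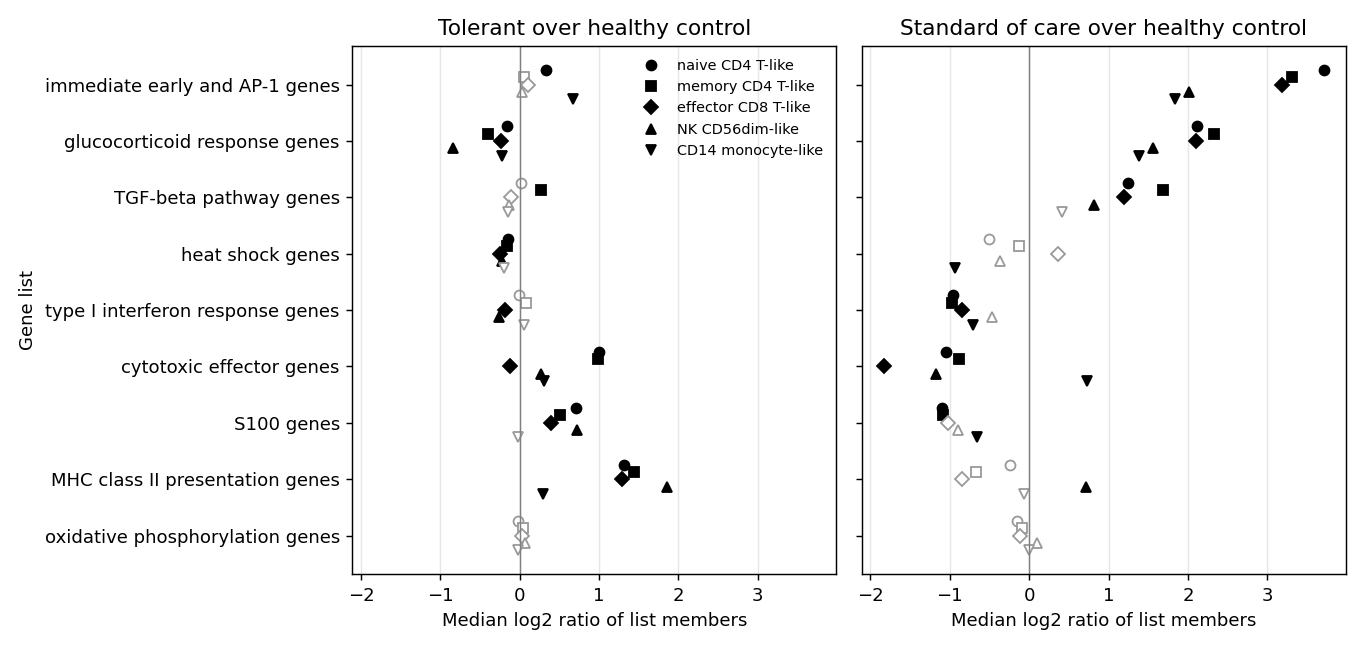
Median log2 ratio of the measured members (x axis) of 9 fixed gene lists (y axis) in 5 classes, for tolerant over healthy control (left) and standard of care over healthy control (right). Filled symbols lie outside the central 95% of 10000 matched random lists; immediate early and AP-1 genes reach 3.71 on the right, and MHC class II genes 1.85 on the left.

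Single genes by which the healthy control library stood apart from both transplant libraries included GZMB, XCL2, NSG1 and GBP5. In effector CD8 T-like cells GZMB, the granzyme B gene and a fixed marker of NK CD56dim cells, stood at 922 CPM (900 to 944) against 179 in both the standard of care and the tolerant library, and SPON2, a marker of the same cells, at 216, 48.7 and 64.2 CPM. XCL2, a chemokine gene and fixed marker of NK cells, stood at 16.5 CPM there, against 85.0 and 128 CPM, and NBL1 at 0.682, 53.3 and 7.49 CPM. In NK CD56dim-like cells NSG1 (51.3, 11.6 and 4.22 CPM) and LINC00299 (135, 33.0 and 42.8 CPM) were higher. PRSS57, a fixed marker of progenitors (9.30, 144 and 50.4 CPM) and LAG3, an inhibitory receptor gene (17.2, 70.3 and 69.9 CPM), were lower. LINC00299 was among the top 10 genes of cluster 6 and PRSS57 among those of cluster 4. Cluster 6 held 787 of 1094 NK CD56dim-like cells in the healthy control, 116 of 805 in the standard of care and 470 of 1197 in the tolerant library. The named genes were not examined within single clusters, so the cluster mix could account for part of such differences. In naive CD4 T-like cells SSBP2 (75.5, 27.2 and 26.2 CPM) and TMIGD2 (52.2, 23.3 and 19.6 CPM) were higher. In the same cells GBP5, an interferon-induced GTPase gene (50.7, 156 and 149 CPM), and PRDM1, which encodes the transcription factor Blimp-1 (12.98, 72.8 and 41.0 CPM), were lower. In memory CD4 T-like cells NSG1 (83.1, 20.2 and 21.6 CPM) and WDR86-AS1 (80.0, 18.3 and 22.4 CPM) were higher. ATP8A1 (14.03, 68.2 and 54.6 CPM) and NBL1 (5.89, 63.1 and 22.6 CPM) were lower. In CD14 monocyte-like cells TMEM176B (92.7, 28.0 and 8.14 CPM) and NBPF14 (194, 71.4 and 71.1 CPM, of a multicopy family and therefore uncertain) were higher, and FOLR3 and GBP5 (19.4, 123 and 70.7 CPM) lower.

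Oxidative phosphorylation genes, which serve energy metabolism, had medians between -0.05 and 0.10 for tolerant over healthy control in the 8 cell sets examined. In B-like cells the same list had medians of -0.47 for standard of care over healthy control and 0.40 for tolerant over standard of care. Over all kept cells, B cell receptor and activation genes had a median of 0.33 for tolerant over healthy control and -0.52 for tolerant over standard of care, and erythrocyte genes medians of -1.14 and -3.06. Monocyte genes over all kept cells had a median of -0.56 for tolerant over healthy control, and platelet genes of -0.32. Cell cycle genes (4 of 11 members measured) and neutrophil genes (2 of 7) had too few measured members for a median. With median-of-ratios scaling in place of total counts, the median of all genes moved by up to 0.13 for standard of care over healthy control and by -0.20 for tolerant over standard of care, so small list medians against the standard of care library are relative to the scaling.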

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

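The heat shock test was chosen only after the results had been seen, while the GC content and free RNA tests were written before. Barcodes with under 200 detected genes were left out of the comparisons, but in the standard of care library they made up 7.97% of barcodes (408 of 5118, 95% interval 7.24 to 8.75%), against 0.541% in the healthy control and 0.390% in the tolerant library, which drew attention to them. Haemoglobin genes held 92.0% of their counts in the standard of care library, 88.3% in the healthy control and 83.6% in the tolerant library, so most of these barcodes carried erythrocyte RNA. Among kept cells haemoglobin genes held 0.374%, 0.0918% and 0.0404% of the counts in the same order.

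Immediate early and glucocorticoid response genes were higher in the standard of care than in the healthy control library in the 5 classes, and so were NF-kB genes in the 4 of them where that list had enough measured members, naive CD4 T-like cells being the exception. A trend with GC content or transcript length is argued against, since the lowest of the 5 corrected medians was still 1.86. Free RNA stays open. The extra level of a list member in the highest class was, as a median over 25 members, 3.37 times that in the second lowest class. This lay above the bound of 3 set beforehand, but its interval of 2.06 to 6.105, from resampling the members, includes that bound. HBB, which is not made by these classes, differed 22.5-fold between the same ranks. Whether that HBB was free RNA was not tested, but RNA from other cells need not be spread evenly, so the bound cannot decide. The interval and the HBB value were looked up only after the median had been seen. Handling, software version and depth cannot be told apart from the group, since 1 library holds them together; heat shock genes, which handling can also induce, reached a median of at most 0.37, which excludes nothing, and a transplant or drug effect remains an untested candidate explanation.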

How the results depend on the processing

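Removal of the trend with GC content and length, each cluster taken alone, and the tolerant against the healthy control library alone were chosen after the results had been seen. Where direction or size shifted with a setting, the cause was not tested. No paired analysis was possible because each group has 1 library and no replicate number links them.

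Without integration the standard of care library split off: its shares were 0% for B-like, 0% for MAIT-like, 0.0224% for NK-like, 13.8% for T-like, 0.0224% for memory CD4 T-like and 0% for naive CD4 T-like cells, so most of its lists within T, NK and B classes had no value. In the healthy control NK-like cells were then 15.1%, memory CD4 15.9% and naive CD4 T-like cells 11.04%, and in the tolerant library NK-like cells 17.7%, memory CD4 19.5%, naive CD4 T-like cells 2.48% and CD14 monocyte-like cells 5.31%. Of the 70 entries named by the size rule, 11 were named again, and classes with too few standard of care cells could not be compared. For tolerant over healthy control in memory CD4 T-like cells, GNLY was then -0.46, CX3CR1 -0.68, the cytotoxic list -0.42 and the naive and central memory list 0.025. CXCL10 in CD14 monocyte-like cells was -0.74 against the healthy control and -1.35 against the standard of care library, and the MHC class II median there was 0.15.

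Without doublet removal B-like cells were 9.47% of the tolerant library. CD14 monocyte-like cells were 10.8%, 11.8% and 6.43% of the healthy control, standard of care and tolerant libraries, memory CD4 13.7%, 16.1% and 19.6%, and naive CD4 T-like cells 14.6%, 15.03% and 9.13%. With at least 500 genes and at most 10% mitochondrial counts, T-like cells were 62.6%, 56.9% and 58.2%, and in the standard of care library CD14 monocyte-like cells were 9.12%, NK-like cells 20.01% and memory CD4 T-like cells 16.3%.

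At resolution 0.5 memory CD4 T-like cells were 19.3%, 22.0% and 26.4% and naive CD4 T-like cells 8.87%, 8.67% and 2.25% in the same order. At resolution 2 memory CD4 T-like cells were 11.1%, 13.2% and 11.1%, NK-like cells were 15.9% of the tolerant library, and CX3CR1 in memory CD4 T-like cells was -0.14. With counts thinned memory CD4 T-like cells were 10.05%, 12.8% and 10.1%, and CX3CR1 was -0.32. At resolution 2 and when thinned, the excess of memory CD4 T-like cells in the tolerant over the healthy control library was thus absent, and their share was lower in the tolerant than in the standard of care library.

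With a minimum of 10 CPM in the size rule, 43 of its 70 entries were named again. With no minimum the regulatory T list in effector CD8 T-like cells was 0.032 against the healthy control, and against the standard of care library the calcineurin-NFAT list in memory CD4 T-like cells was 0.030 and the B cell receptor list over all cells 0.18. For tolerant over healthy control, cluster 2 alone gave 0.11 for the regulatory T list and 0.10 for the naive and central memory list in memory CD4 T-like cells, and the cytotoxic list in effector CD8 T-like cells was 0.16 in cluster 0 alone and -0.11 in cluster 1 alone. Among CD14 monocyte-like cells, cluster 19 alone gave -0.48 for the cytotoxic and 0.19 for the glucocorticoid list against the healthy control, -0.78 for heat shock and 0.038 for B cell receptor genes against the standard of care library, and -0.076 for platelet RNA in standard of care over healthy control. Cluster 5 alone gave 0.36 for the cytotoxic list against the standard of care library.

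Counting each result once per setting, 309 comparisons of shares stayed within the counting interval and 87 moved, and 967 comparisons of gene values stayed, 75 moved and 6 changed direction. For list medians outside the central range of random lists, 14 comparisons changed direction and 84 fell inside that range. For medians inside the range, 83 comparisons left it in the same direction. The other 2164 were counted as unchanged, which for medians inside the range includes any change of sign. MAIT-like cells stayed between 0.275% and 0.425% of the tolerant library and plasma cell-like cells between 0.635% and 0.707%. The MHC class II median for tolerant over healthy control lay between 1.36 and 1.87 in NK CD56dim-like, 0.69 and 1.47 in naive CD4, 0.80 and 1.47 in memory CD4 and 0.94 and 1.46 in effector CD8 T-like cells, and the immediate early median for standard of care over healthy control between 2.32 and 4.29 in naive CD4 T-like cells, while the NF-kB median ranged from 0.27 to 2.97 in memory CD4 and from 1.04 to 3.19 in effector CD8 T-like cells.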

Other observations

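B-like cells of the tolerant library carried more immediate early RNA than those of the healthy control. Of 13 immediate early and AP-1 genes 7 were at least 1 log2 unit higher, with a median of 1.14 at percentile 100. In B-like cells of the standard of care library 10 of 13 were at least 1 unit higher, with a median of 2.91. The tolerant over healthy control median was also raised in CD14 monocyte-like (0.67, percentile 100) and naive CD4 T-like cells (0.33, percentile 99.9). It lay between -0.01 and 0.11 in NK CD56dim-like, memory CD4 T-like, effector CD8 T-like and CD16 monocyte-like cells. EGR1 stood at 150 CPM in the tolerant (139 to 162), 11.8 in the healthy control (7.59 to 17.6) and 6.33 in the standard of care library (0.767 to 22.9), and FOS at 104, 10.4 and 801 CPM. A B sub-cluster without a name, led by EGR1, DHRS9, DUSP2 and EBI3, held 74 cells of the tolerant, 3 of the healthy control and 0 of the standard of care library.

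TNFRSF9, which encodes the activation receptor 4-1BB, stood at 34.1 CPM in tolerant NK CD56dim-like cells (29.2 to 39.7), 2.62 in the healthy control (1.31 to 4.69) and 6.86 in the standard of care library (3.92 to 11.1). Cluster 20, left without a name and led by IFIT2, OASL, PMAIP1, HERC5, TNF and IFNG, held 205 standard of care, 9 healthy control and 11 tolerant cells; with 1 library per group, such a cluster reflects that library as much as a cell state. TUBB1, a platelet tubulin gene, stood at 85.7 CPM in tolerant CD14 monocyte-like cells, 18.8 in the healthy control and 34.6 in the standard of care library, whereas PPBP in CD16 monocyte-like cells stood at 64.5, 54.7 and 64.3 CPM.

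The MAIT tests on cells placed in other clusters and on dilution, and the HLA allele test, were chosen or reworded after the results had been seen. MAIT-like cells were fewer in the tolerant library than in both others. Against the healthy control, misplaced cells are argued against as the whole cause: TRAV1-2, SLC4A10 and COLQ summed over all kept cells had a ratio of 0.253 (0.231 to 0.277), but the ratio of shares was 0.0884, so placement could account for part of the difference. Dilution by other T cells is also argued against, since the fold of MAIT-like cells was 6.98 times the larger of those of regulatory and gamma-delta T-like cells. Against the standard of care library the ratio was 1.10 (0.935 to 1.30), and true loss and different placement cannot be told apart there. T cell receptor alpha genes as a whole were lower in that library (204 CPM, against 785 in the healthy control and 663 in the tolerant library). That limit covers TRAV1-2 only, and the members went apart. TRAV1-2 stood at 8.60 CPM in the tolerant and 5.80 in the standard of care library, SLC4A10 at 1.14 and 2.90, and COLQ at 3.095 and 2.96. The test was first set for both comparisons together and gave a different result in each. A difference between persons, treatment included, remains an untested candidate explanation.

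MHC class II genes were higher in T and NK cells of the tolerant than of the healthy control library. RNA of B-like and CD14 monocyte-like cells is argued against as the whole cause. It accounted for at most 33.1% of the extra level, in naive CD4 T-like cells (counting interval 21.7 to 44.5%). In NK CD56dim-like, memory CD4 and effector CD8 T-like cells it accounted for 2.48%, 9.51% and 1.55%. RNA of CD16 monocyte-like and dendritic cell-like cells was not estimated on its own. A different mix of clusters is argued against as the whole cause by the lowest single-cluster median of 0.80. It could account for part: in memory CD4 T-like cells clusters 2 and 8 gave 1.09 and 0.80, against 1.44 for the class. Both clusters also lay below the class median in naive CD4 T-like and NK CD56dim-like cells. In effector CD8 T-like cells clusters 0 and 1 gave 0.94 and 1.46, against 1.29. Better mapping of HLA alleles is argued against by a median of at most 0.29 in B-like and monocyte-like cells, although cluster 19 alone, a small part of the CD14 monocyte-like cells, gave 0.83. No biological explanation was tested, and the pattern was found and examined in the same 2 libraries.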
